A study of Danio rerio with 2 samples.

How the data were processed

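Single-cell RNA sequencing was carried out on cells of zebrafish (Danio rerio) tails at 20 hours post fertilisation (hpf), sorted for the fluorescence of an npas4l reporter. Npas4l, the product of the cloche locus, is a transcription factor required in zebrafish for the formation of endothelial and blood cells. Per the labels' protocols, tails of about 150 embryos were cut off, dissociated and sorted for GFP with exclusion of DAPI-positive dead cells; whether this number is per genotype or for both is not clear from the labels. The heterozygous sample came from npas4lbns423/+ embryos and the mutant sample from embryos carrying both the bns423 and the bns297 allele. Each sample was loaded on a droplet lane of its own with the aim of 5000 cells. There was 1 library per genotype.

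The submitters' processing notes name STARsolo, Scanpy and the zebrafish genome build danRer11. Tool versions, the annotation, the cell filters, the treatment of doublets and the clustering settings are not given in the sources used here. Both deposited tables hold 1 row per cell, and the cell's genotype is written in each row. The authors' genes per cell are counts, per the file headers. The authors deposited the total counts of each cell, here called UMIs (unique molecular identifiers), as the natural log of the total plus 1, per the file headers. The deposited mitochondrial values are percent of a cell's UMIs, per the file headers. The authors also deposited a coarse and a fine Leiden cluster number for every cell. The second table adds initial spliced and unspliced sizes per cell, which are whole numbers and are read here as UMIs, and RNA velocity scores deposited by the authors (velocity pseudotime, root cell score, end point score and self-transition), per the file headers. RNA velocity compares unspliced with spliced transcripts to order cells along a trajectory. The velocity tool and its settings are not given in the sources used here. The tables analysed here pair no cluster number with a cell type name, so clusters are named by number only. Gene expression was not analysed here, so marker genes were not used, no cell cycle phase was compared, and the genotype labels were not checked against npas4l itself. The design, the named items, the rule of size and the alternatives given below without another remark were set before the data were examined. The named items were all clusters with at least 20 cells over both libraries, which all 8 coarse and 15 fine clusters met. Medians per cluster were given for a library with at least 20 cells in it, so the 11 heterozygous cells of cluster 6 have none.

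Total UMIs were recovered by inverting the log and rounding. The inverted values lay within 0.0614 of a whole number. The 10469 cells of the first table were matched to the second by genotype and barcode. All 10469 had identical values in the 6 measures compared. These included the cluster numbers and the recovered UMIs, whose agreement follows from that of the log totals. Barcodes of 5 cells, which occurred in both libraries, carried an added suffix in the second table. No cell had fewer than 5267 UMIs or 925 genes or more than 5.94% mitochondrial UMIs. The percent of unspliced UMIs was computed as unspliced over spliced plus unspliced UMIs. The sum of spliced and unspliced UMIs was 101% of the deposited total in the median cell, so the percent is a ratio of separately counted classes.

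Shares of cells were computed per library with exact (Clopper-Pearson) 95% intervals, and medians over cells with exact 95% intervals from order statistics. The difference in composition is the sum over clusters of the absolute differences in share, divided by 2, with an interval from 2000 multinomial resamples of cells. All of these intervals cover counting error over cells only. Cells are not replicates, so no p-value was computed and no interval covers the spread between embryos, sorts or lanes. By the rule of size, a cluster was called different where the shares differed at least 2-fold, the exact intervals did not overlap and both libraries together held at least 20 cells. Bounds of a ratio of shares were taken from the opposite ends of the exact intervals.

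The alternatives were the second table, minimums of 14240 UMIs and of 2967 genes per cell (the medians of the library with the lower value), matching on 10 bins of UMIs with equal weight (judged on the ratio and the number of cells alone), a maximum of 1.39% mitochondrial UMIs (the median of all cells), removal of the 5% of each library's cells with the most UMIs in place of a doublet call, leaving cluster 1 out of the denominator, the fine clusters, means in place of medians, and medians averaged over clusters. Leaving out clusters 1 and 4 together, quality and score medians without cluster 1, averaging the velocity scores over clusters, and averaging over all 8 clusters with cluster 6 included were chosen after seeing the data. So were the sets of clusters whose shares are given together. The cuts of 0.05 in pseudotime and of 0.9 in the root cell and end point scores were not part of the planned design. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.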

Results

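Cells sorted for an npas4l reporter were profiled from tails of npas4l heterozygous and npas4l mutant zebrafish embryos at 20 hpf. The comparison addresses where cells that have switched on npas4l end up when the embryo carries a working copy of the gene and when both copies are mutant. The heterozygous library held 5207 cells and 115131011 UMIs. The mutant library held 5262 cells and 84294688 UMIs. With 1 library per genotype, every interval below covers counting error over cells only. The cells had been divided by the authors into 8 coarse clusters, numbered from the largest to the smallest, and 15 fine clusters.

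The libraries occupied largely different clusters. Clusters 1 and 4 together held 78.5% of the heterozygous cells (95% interval 77.3% to 79.6%) and 3.23% of the mutant cells (2.77% to 3.74%). Clusters 2, 3 and 6 together held 9.14% of the heterozygous cells (8.37% to 9.96%) and 69.5% of the mutant cells (68.3% to 70.8%). Clusters 5, 7 and 8 held the remaining 12.4% (11.5% to 13.3%) and 27.2% (26.0% to 28.5%). These sets of clusters were formed after seeing the data, and cluster 2 parted from clusters 3 and 6 under another denominator given below. Summed over clusters, 75.3% of the cells (74.0% to 76.5%) would have to change cluster to turn one composition into the other. By the rule of size, 7 of the 8 coarse clusters differed, of which 2 were larger in the heterozygous library and 5 in the mutant library.

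**Figure D1:**
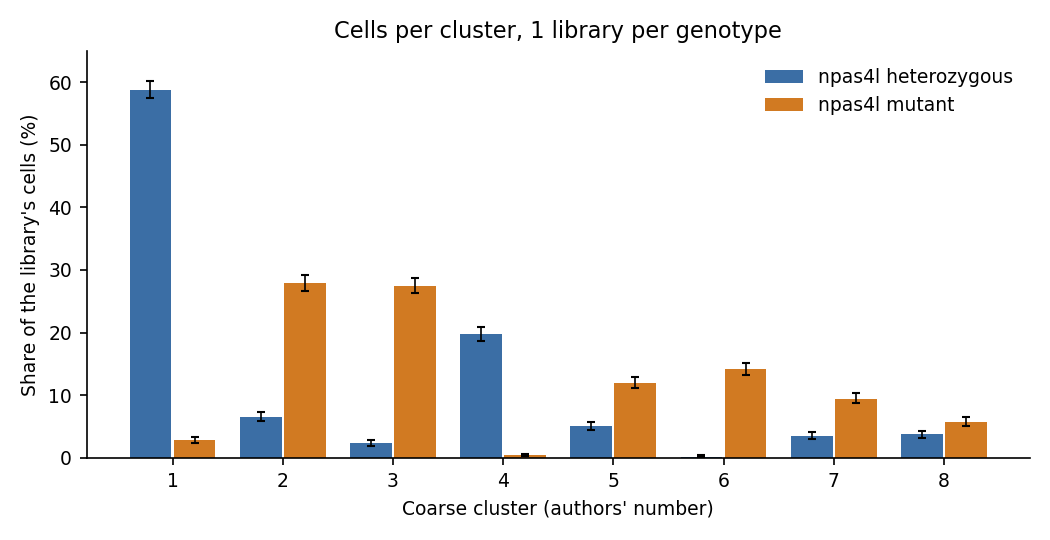
Share of each library's cells (%) in the 8 coarse clusters, with blue bars for the npas4l heterozygous library (5207 cells) and orange bars for the npas4l mutant library (5262 cells). Error bars are exact 95% intervals for counting error. Shares of clusters 1 and 4 are higher in the heterozygous library and shares of the other 6 clusters in the mutant library.

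Cluster 1 was the largest cluster of the heterozygous library, with 3060 cells or 58.8% (57.4% to 60.1%). In the mutant library it held 147 cells or 2.79% (2.37% to 3.28%), a share 21.0-fold lower. Cluster 4 held 1027 heterozygous cells, 19.7% of that library (18.7% to 20.8%), and 23 mutant cells, 0.437% (0.277% to 0.655%), a 45.1-fold difference. Its main fine clusters, numbers 3, 10 and 11, were all smaller in the mutant library. Fine cluster 3 held 731 heterozygous and 14 mutant cells, fine cluster 10 held 163 and 4, and fine cluster 11 held 132 and 5. No difference in their proportions within cluster 4 was detectable with 23 mutant cells. Fine cluster 3, for example, made up 71.2% of cluster 4 in the heterozygous library (68.3% to 73.9%) and 60.9% in the mutant library (38.5% to 80.3%).

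Cluster 6 had the highest ratio of mutant to heterozygous share. It held 743 mutant cells, 14.1% of the library (13.2% to 15.1%), against 11 heterozygous cells, 0.211% (0.106% to 0.378%). The ratio was 66.8, with bounds of 34.9 and 143. Cluster 3 held 27.5% of the mutant cells (26.3% to 28.7%) and 2.34% of the heterozygous cells (1.95% to 2.79%), a ratio of 11.7. Cluster 2 held 27.9% of the mutant cells (26.7% to 29.2%) and 6.59% of the heterozygous cells (5.93% to 7.30%), a ratio of 4.24. The 5 fine clusters of cluster 3 were each larger in the mutant library, with ratios from 8.91 in fine cluster 7 to 43.5 in fine cluster 8. Within cluster 3, fine cluster 8 stood apart. It made up 18.2% of the mutant cells of cluster 3 (16.3% to 20.3%) and 4.92% of the heterozygous ones (1.83% to 10.4%, 6 cells). The intervals of fine clusters 4, 6, 7 and 9 within cluster 3 overlapped between the libraries.

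Cluster 5 held 12.0% of the mutant cells (11.1% to 12.9%) and 5.07% of the heterozygous cells (4.49% to 5.70%), a ratio of 2.37. Cluster 7 held 9.46% (8.69% to 10.3%) and 3.55% (3.07% to 4.09%), a ratio of 2.66. Cluster 8 held 5.78% (5.16% to 6.44%) and 3.74% (3.25% to 4.30%), and its ratio of 1.54 did not reach the rule of size, although it did in cells above the UMI minimum (2.35), above the gene minimum (2.25) and below the mitochondrial maximum (2.12). Its fine clusters 5 and 12 divided it alike in both libraries, fine cluster 12 making up 11.3% of the heterozygous (7.21% to 16.6%) and 10.9% of the mutant cells of cluster 8 (7.59% to 14.9%).

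Shares within a library sum to a fixed total, so the size of cluster 1 in the heterozygous library lowers every other share there. Among the cells outside cluster 1, cluster 5 held 12.3% of the heterozygous cells (10.9% to 13.8%) and 12.3% of the mutant cells (11.4% to 13.3%). Cluster 7 held 8.62% (7.46% to 9.88%) and 9.74% (8.94% to 10.6%), and cluster 8 held 9.08% (7.90% to 10.4%) and 5.94% (5.31% to 6.63%). Outside clusters 1 and 4, a denominator chosen after seeing the data, cluster 2 held 30.6% (27.9% to 33.4%) of the heterozygous and 28.8% (27.6% to 30.1%) of the mutant cells. Clusters 5 and 7 turned direction under it, cluster 5 with 23.6% (21.1% to 26.2%) of the heterozygous and 12.4% (11.5% to 13.3%) of the mutant cells, and cluster 7 with 16.5% (14.4% to 18.8%) and 9.78% (8.98% to 10.6%). Of the 6 clusters left, numbers 3 and 6 remained more than 2-fold larger in the mutant library under this denominator, with ratios of 2.61 and 14.9. Cluster 8 was 2.92-fold larger in the heterozygous library. The ratios of the fine clusters of cluster 3 fell as well, to between 1.98 in fine cluster 7 and 9.68 in fine cluster 8. The shares rest on a GFP gate, a set number of cells per lane and clusters whose defining genes are not known here and can themselves differ by genotype, and with 1 library each, a cluster mostly of 1 library can be that library and not a cell type. The ratios also changed with the UMIs of the cells taken. In cells matched on UMIs, the ratios of clusters 5 and 7 were 1.54 and 1.72, which left 3 clusters at least 2-fold larger in the mutant library. In cells above the UMI minimum the ratios of clusters 4 and 6 were 0.0487 and 22.7. Heterozygous cells of cluster 1 had the most UMIs, as described next. Matching lowered the heterozygous share of cluster 1 from 58.8% to 46.0%, so the matched ratios do not separate depth from composition.

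Heterozygous cells had more UMIs. The median heterozygous cell had 20744 UMIs (20430 to 21139) and 3286 genes (3262 to 3309). The median mutant cell had 14240 UMIs (14084 to 14403) and 2967 genes (2953 to 2985). The heterozygous cells of cluster 1 had a median of 25372 UMIs (24966 to 25677), more than either library had in any other coarse cluster. Without cluster 1 the median was 14013 UMIs in the heterozygous and 14149 in the mutant library. In clusters 2, 3, 5, 7 and 8 the ratio of mutant to heterozygous median UMIs lay between 0.966 and 1.02, with overlapping intervals in all 5. The ratio of median genes in these 5 clusters lay between 0.987 and 1.01, again with overlapping intervals. Mutant cells assigned to cluster 1 had a lower median, 17072 UMIs (16511 to 18379). The mutant cells of cluster 6 had the lowest median, 11771 UMIs (11569 to 11937).

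**Figure D2:**
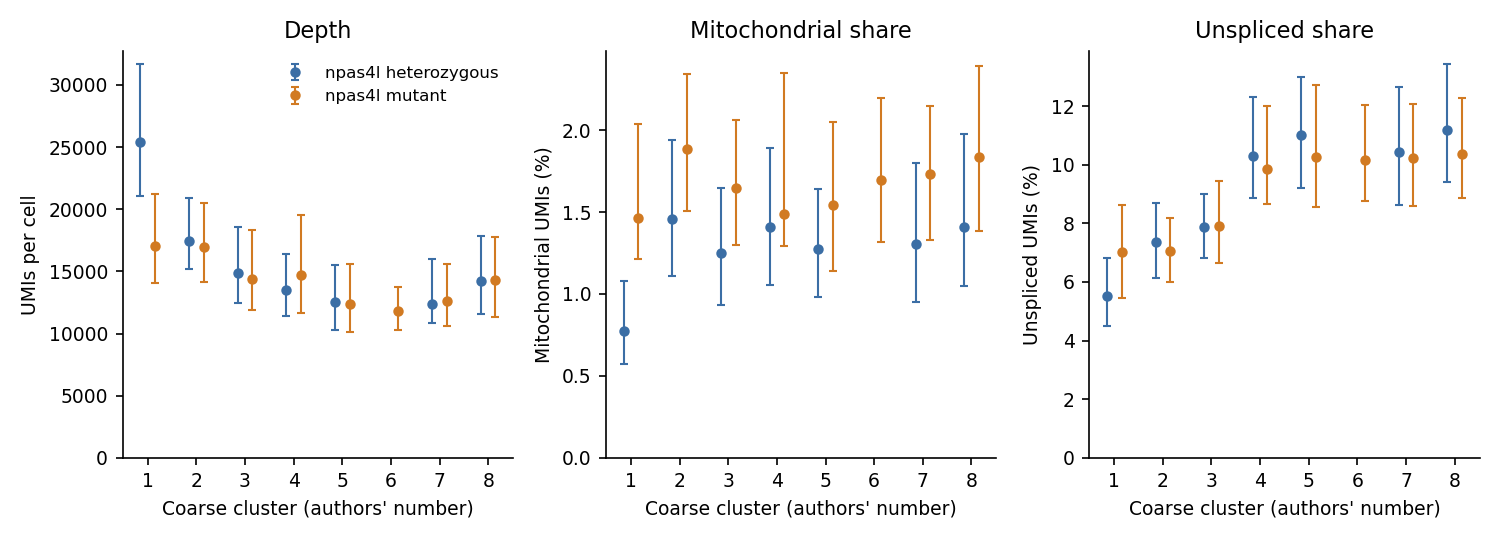
UMIs per cell, mitochondrial UMIs (%) and unspliced UMIs (%) by coarse cluster, for heterozygous (blue) and mutant (orange) cells. Points are medians over cells, bars run from the lower to the upper quartile, and the 11 heterozygous cells of cluster 6 are not drawn. Heterozygous cells of cluster 1 have the most UMIs and the lowest mitochondrial and unspliced percents, and mutant medians of the mitochondrial percent are higher in all 7 clusters drawn for both libraries.

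Mitochondrial transcripts made up 0.994% of UMIs in the median heterozygous cell (0.976% to 1.01%) and 1.73% in the median mutant cell (1.70% to 1.75%). The mutant median was higher in all 7 coarse clusters with at least 20 cells in each library, and the intervals lay apart in 6 of them. The difference was 0.685 percentage points in cluster 1, where the medians were 0.776% and 1.46%. It was between 0.270 and 0.428 percentage points in clusters 2, 3, 5, 7 and 8. In cluster 4, with 23 mutant cells, the intervals overlapped.

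Unspliced transcripts separated the clusters into those with few and those with many. Heterozygous cells of cluster 1 had a median of 5.53% unspliced UMIs (5.45% to 5.60%), and cells of clusters 2 and 3 had medians between 7.07% and 7.91% over both libraries. In clusters 4, 5, 6, 7 and 8 the medians lay between 9.86% and 11.2%. The library medians were 6.88% in heterozygous and 8.44% in mutant cells. Within clusters, intervals lay apart only in cluster 1, where mutant cells had the higher median, 7.02% (6.51% to 7.30%). Cluster 3 had 7.88% in heterozygous and 7.91% in mutant cells, and in the other 5 of the 7 clusters compared the mutant median was the lower one, with overlapping intervals. The cluster 1 medians lay closer together in cells with 12000 to 18000 UMIs, a window chosen after seeing the data. They were 6.26% in 275 heterozygous and 6.67% in 61 mutant cells. No interval was computed there, so the cluster 1 difference is not separated from depth.

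Velocity pseudotime, the authors' ordering of all cells from 0 to 1, placed the genotypes apart as wholes. The median was 0.0136 in heterozygous and 0.461 in mutant cells. Within the 7 coarse clusters compared, mutant minus heterozygous medians lay between -0.0159 and 0.00652, with intervals apart in clusters 1, 2, 3 and 7. Cluster 1 lay at the start, with medians of 0.0117 in heterozygous and 0.00961 in mutant cells. It held 3187 of the 3194 cells with a pseudotime of 0.05 or less. This cut lies between the upper quartile of cluster 1, 0.0129, and the lower quartile of cluster 4, 0.274, so the count largely restates cluster membership. Cluster 4 followed at 0.289 and 0.292. Clusters 2, 3, 5 and 7 lay between 0.438 and 0.544 in both libraries, mutant cells of cluster 6 lay at 0.463, and cluster 8 was last, at 0.855 and 0.839. End point scores of 0.9 or more were given to 244 cells, of which 144 were in cluster 8 and 100 in cluster 2. In cluster 8 these were 66 of 195 heterozygous and 78 of 304 mutant cells, and in cluster 2 they were 18 of 343 and 82 of 1469. Such cells made up 28.9% of cluster 8 and 5.52% of cluster 2, whose median end point score was 5.07e-05. No cell of cluster 6 reached 0.9, but its upper quartile was 0.399, against 1.10e-04 in cluster 2. Mean end point scores were 0.419 in cluster 8, 0.204 in cluster 6, 0.0988 in cluster 4 and 0.0946 in cluster 2.

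**Figure D3:**
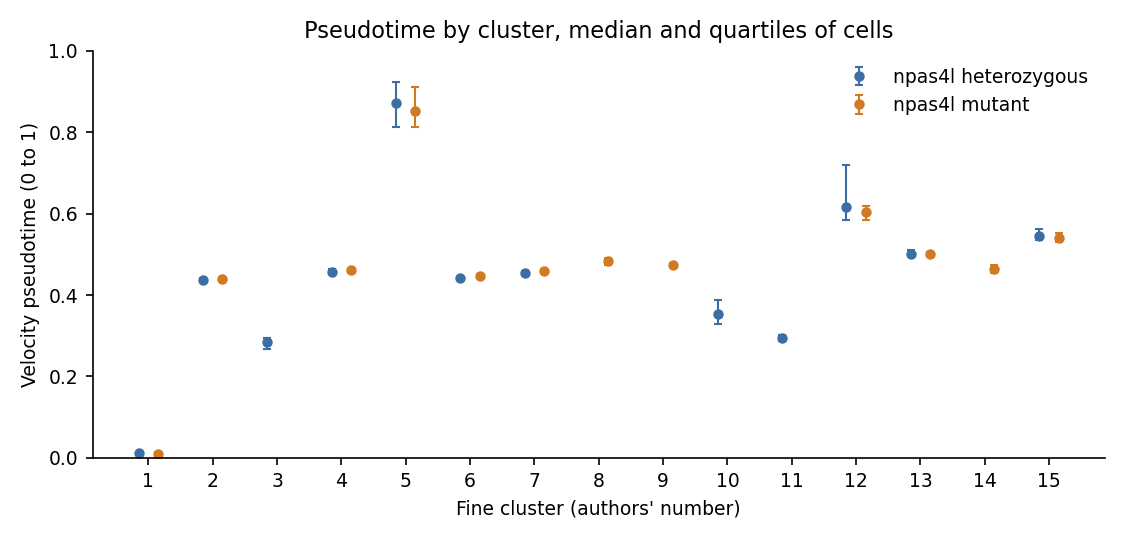
Velocity pseudotime (0 to 1, no unit) by fine cluster for heterozygous (blue) and mutant (orange) cells. Points are medians over cells, bars run from the lower to the upper quartile, and libraries with fewer than 20 cells in a cluster are not drawn. Fine cluster 1 lies near 0 and fine cluster 5, the larger part of coarse cluster 8, has medians of 0.872 and 0.852.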

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

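Leaving out clusters 1 and 4, dropping cluster 1 from medians, averaging velocity scores and averaging over all 8 clusters were chosen after seeing the data. The second deposited table gave identical values, and removing the 5% of cells with the most UMIs moved no count of clusters. Over the 6 alternatives that kept all clusters in the denominator, each of the 8 coarse clusters kept the direction of its ratio of shares. The second table was among these 6 and could not move a ratio. The ratio ranged from 0.0466 to 0.0712 in cluster 1, 4.05 to 5.81 in cluster 2, 9.12 to 17.7 in cluster 3 and 0.0174 to 0.0487 in cluster 4. It ranged from 1.54 to 4.25 in cluster 5, 22.7 to 79.4 in cluster 6, 1.72 to 4.06 in cluster 7 and 1.20 to 2.35 in cluster 8. The difference in composition was 79.8% with the UMI minimum, 79.3% with the gene minimum, 80.2% with the mitochondrial maximum and 69.0% with matched UMIs, where 3 clusters were at least 2-fold larger in the mutant library; the 3 filters gave 6, and the cause was not tested. Fine clusters gave 9 larger in the mutant and 4 in the heterozygous library, out of more clusters. Without cluster 1 the counts were 2 and 1 and the difference 50.5%, and cluster 8 (0.654) and fine cluster 5 (0.658) reversed. Without clusters 1 and 4 the counts were 2 and 1 and the difference 31.1%, and clusters 2 (0.942), 5 (0.526), 7 (0.592) and 8 (0.343) and fine cluster 5 (0.345) reversed, by the change of denominator. The order below is means, medians averaged over 7 clusters with enough cells, over all 8, and medians without cluster 1. The ratio of UMIs per cell was 0.725, 0.928, 0.895 and 1.01 (reversed). That of genes was 0.920, 1.01 (reversed), 0.984 and 0.970. Its direction when averaged rested on 11 heterozygous cells (cluster 6) and 23 mutant ones (cluster 4). In the same order the mitochondrial difference was 0.683, 0.388, 0.399 and 0.352 percentage points, the unspliced difference 1.33, -0.137, -0.264 and -1.38 (the last 3 reversed) and the pseudotime difference 0.294, -0.00157, -0.00237 (both reversed) and 0.0326. The averaged settings give each cluster used the same weight in both libraries and the last leaves cluster 1 out; the cause of the shift with means was not tested. Over all ratios of shares and the root cell, end point and self-transition differences, 78 values stayed within the interval of the reported one. Of the others, 65 moved and 7 whose reported bounds excluded 1 reversed, those named above. For the counts of clusters, the composition, the quality measures and pseudotime, 17 stayed, 26 moved and 7 reversed. Both tallies of values that stayed include the second table, whose identical cells fixed its outcome in advance. Fine cluster 12, whose reported ratio of 1.48 had bounds on both sides of 1 (0.676 and 3.32), also turned direction, to 0.630 without cluster 1 and 0.330 without clusters 1 and 4. No library could be left out, because each genotype had 1, and the planned comparison of cell cycle phase was not run. Counting error limits clusters 4 and 6, with 23 mutant and 11 heterozygous cells.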

Other observations

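The averaging of mitochondrial medians over clusters was planned; the other tests in this part were chosen after the results were seen. Intervals cover counting error over cells only.

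Over all cells of cluster 1, the median number of genes was 3448 in heterozygous and 3256 in mutant cells. Between 12000 and 18000 UMIs, a window that takes 275 of 3060 heterozygous cells, below their lower quartile of 21047 UMIs, and 61 of 147 mutant cells around their median, the order was the opposite: 61 mutant cells had a median of 3068 genes (3041 to 3149) and 275 heterozygous cells had 2822 (2786 to 2880), with median UMIs of 15678 and 16075. Over all cells of cluster 1, the median root cell score was 0.0976 in mutant and 0.0112 in heterozygous cells. The 23 mutant cells of cluster 4 also had a higher root cell score, 0.128 (0.0507 to 0.294) against 0.0109 (0.00798 to 0.0142), while in cluster 7 the mutant median was lower, 0.0635 (0.0436 to 0.0798) against 0.103 (0.0829 to 0.113). In clusters 2, 3, 5 and 8 the intervals of the median root cell score overlapped. In the same depth window, cluster 2 had a median of 2800.5 genes in heterozygous and 2781 in mutant cells. Cluster 5 had 3228 and 3233, cluster 7 had 3226 and 3236, and cluster 8 had 3187 and 3226. Cluster 3 leaned the same way as cluster 1, with 2919 (2862 to 3030) and 3042.5 (3011 to 3068), and these intervals overlapped. Cluster 4 had 3150.5 and, in 8 mutant cells, 3254. Cluster 6 went the other way, with 3329.5 in 6 heterozygous cells and 3062 in mutant cells.

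Of the 257 cells with a root cell score of 0.9 or more, 134 were in cluster 1, the largest cluster, 50 in fine cluster 9 and 35 in cluster 7. Cluster 1 lay at the start of pseudotime, but its median root cell score was 0.0124. Clusters 3, 5, 6 and 7 had higher medians, 0.0505, 0.114, 0.0748 and 0.0785, and clusters 2, 4 and 8 had lower ones. Fine cluster 9, with 163 of its 173 cells from the mutant library, had the highest median root cell score, 0.772, and a median pseudotime of 0.474. Of its cells, 28.9% (22.3% to 36.3%) scored 0.9 or more, namely 9 of the 10 heterozygous and 41 of the 163 mutant cells. The share was 4.18% (3.51% to 4.93%) in cluster 1, with 126 of 3060 heterozygous and 8 of 147 mutant cells. In cluster 3, which includes fine cluster 9, the share was 4.40% (3.44% to 5.53%), with 17 of 122 heterozygous and 52 of 1447 mutant cells. It was 5.12% (3.59% to 7.06%) in cluster 7, with 15 of 185 heterozygous and 20 of 498 mutant cells. In fine cluster 12 it was 9.09% (3.02% to 20.0%). Fine cluster 12, of 55 cells, had the highest median self-transition score, 0.566 (0.531 to 0.586). Its 22 heterozygous cells had a median of 27376 UMIs (17492 to 37330) and its 33 mutant cells 16869 (15306 to 19173), so the intervals overlapped.

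Each library placed some cells in clusters filled mostly by the other, and embryos or cells in the wrong sample would do this. Heterozygous cells mixed into the mutant sample would keep the mix of clusters 1 and 4 if they were like the heterozygous library as a whole. Cluster 1 made up 86.5% (80.4% to 91.2%) of such mutant-library cells and 74.9% (73.5% to 76.2%) in the heterozygous library. At the rate of cluster 4, mixing would give 68.5 cells (43.2 to 103) in cluster 1, where 147 were found. These values argue against mixed-in cells of that average mix as the whole source. Single misplaced embryos could have had another mix, and the intervals do not cover the spread between embryos, so these were not excluded. Likewise there were 23.3 heterozygous cells (20.7 to 26.3) per 100 mutant cells in cluster 2 and 1.48 (0.736 to 2.66) in cluster 6. Mutant cells mixed into the heterozygous sample at the rate of cluster 6 would account for at most 39.1 of the 343 heterozygous cells of cluster 2. This bound also assumes the average mix of the mutant library and covers counting error only. Reads crossing between the libraries would carry shared barcodes, and 0 of the 170 mutant cells of clusters 1 and 4 had a barcode found in the heterozygous library, which by 3 counts of the total allows a share of up to 1.76% (exact upper limit 2.15%). Whether the 147 mutant cells of cluster 1 lie at its border stays open, since 95.9% (91.3% to 98.5%) of them had a pseudotime of 0.05 or less but so did 99.4% of all cells of cluster 1, and a genotype effect, a part played by mixed-in cells and free RNA in droplets were not excluded or not tested.

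The mitochondrial percent was higher in the mutant library. The mix of clusters accounts for part of the gap, since the mean difference over clusters was 0.388 percentage points against 0.732 between the library medians, but not for all, as the intervals lay apart within 6 of 7 clusters. Lower depth is argued against by clusters 2, 3, 5, 7 and 8, where UMIs per cell were alike and the ratio of mitochondrial percents was still at least 1.21. Across these 5 clusters the highest and lowest ratios differed by a factor of 1.095, which a difference in handling between the samples could give and a genotype effect could give too, so for them these cannot be told apart with 1 library per genotype. In cluster 1 the ratio was 1.88 (1.78 to 2.09), above the highest upper bound in these 5 clusters, 1.53. Handling that acted on all clusters by one factor is thus argued against as the whole cause there. The mutant cells of cluster 1 also had fewer UMIs, with a ratio of medians of 0.673. Lower depth, or a different make-up of these cells, therefore stays open for cluster 1. In cluster 4, with 23 mutant cells, the mitochondrial ratio was 1.06.

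Mutant cells had fewer UMIs. Shallower sequencing of the whole library would lower every cluster alike, and the lowest mutant to heterozygous ratio in clusters 2, 3, 5, 7 and 8 was 0.966. The ratio without cluster 1 was 1.01 (0.975 to 1.04), so the library gap is consistent with the near absence of cluster 1 cells in the mutant library. Why the mutant cells within cluster 1 had fewer UMIs than its heterozygous cells was not tested, and genotype stays open.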
